A study of Homo sapiens with 6 samples.

How the data were processed

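RNA was measured by sequencing in HCT116, an established human colorectal carcinoma cell line. The labels describe 3 libraries from control cells and 3 libraries from cells given 1 µM BMH-21 for 24 h. BMH-21 is a DNA-intercalating small molecule that inhibits RNA polymerase I, the enzyme that transcribes the ribosomal RNA genes. Per the labels' protocols, controls received DMSO, while the titles of the control samples give 0 h, so whether the controls were also kept for 24 h was not settled here. The series' design text calls the replicates biological. RNA was extracted with Trizol, and cDNA was primed with random hexamers, per the labels' protocols. The labels name the molecule as polyA RNA, yet the extraction protocol describes removal of ribosomal RNA with a Ribo-Zero kit. The enrichment step is therefore uncertain, which matters for transcripts without a poly(A) tail.

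The deposited values are TPM per gene, a measure of a transcript's share of its library, made by the authors and kept separate for each library. STAR, Salmon and the genome build GRCh38 are named in the submitters' processing notes, without version or role. The annotation, strand setting and any filter are not given in the sources used here. The table lists 25662 gene symbols, and TPM totals over these genes were 990744 to 992038 per library. TPM has length and depth divided out, so the depth of each library is unknown and no counting interval is given. Each value is relative to all other transcripts of its library, so a change in total RNA per cell is not visible. Genes with near-identical copies, such as histones, can share reads, and overlapping or antisense genes cannot be told apart where strand was not used. Of the symbols, 25578 were matched to the GENCODE release 29 annotation of GRCh38 by current symbol and gene ID. A further 17 were matched by the symbol of that release, and 67 were not matched. Coordinates are 1-based, come from that annotation, and span the whole gene.

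The groups were compared with limma 3.58.1 in R 4.3.3. The model was fitted to log2(TPM + 1), with a pseudocount of 1, an intensity trend of the variance and no covariate. Genes were kept where TPM was at least 1 in at least 3 of the 6 libraries. All tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the 12041 genes kept. A gene was called changed at an adjusted p under 0.05. Fold changes on the log2(TPM + 1) scale understate the change of genes with low values. Means and SDs are of TPM over the 3 libraries of a group.

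A total of 24 gene lists were fixed before the data were examined: 21 pathway or gene class lists and 3 lists of markers of other cell types. The 21 lists with at least 5 genes kept were tested with camera in limma, which asks whether the members of a list move differently from the other genes. The preset correlation between genes was 0.01, and the p-values were adjusted over the lists. The same test was run with an estimated correlation. With it, none of these fixed lists had an adjusted p under 0.05, so each call of a fixed list rests on the preset value. This includes the G2/M list, where all 53 measured members were lower (camera adjusted p = 0.19). A call lost in this setting thus does not by itself argue against a list.

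Named genes were chosen by a rule set before the data were examined. It takes a set of focal genes whatever their result, which includes POLR1A, POLR1B, UBTF, RRN3, MDM2, MDM4, CDKN1A, MYC, RPL5, RPL11, RPL22, RPL22L1, NPM1, NCL and FBL. It also takes the 8 genes higher and the 8 genes lower with the largest log2 fold change among called genes. Their groups must not overlap, and the mean TPM must be at least 5 in the group with the higher mean. Rows named only by a clone or database identifier were left out. Last, it takes up to 4 called members of each fixed list with the largest changes. Where a list has no called member, up to 2 members with the highest mean are given as values. Some genes that meet the rule are not reported here. Genes named outside this rule are marked as chosen after their values were seen.

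Before use, the fit was tested on simulated libraries for this comparison, over 12041 genes. It recovered 34.3% of genes simulated with an absolute log2 fold change of 0.5, 74.6% at 1 and 97.0% at 2. Of 143 calls in that simulation, 6 were of unchanged genes, and 1 gene was called where no gene was changed. For log2 fold changes of 0.5, 1 and 2, only 67, 67 and 66 genes were changed, all drawn from genes with higher values. The simulated noise was independent between genes. In the data 4380 genes were called, so these rates do not describe the real comparison.

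Before the data were examined, alternatives were listed for the pseudocount, the filter, the scaling between libraries, the variance trend, a replicate block and each library left out in turn. The scalings were a trimmed mean of log ratios, medians of ratios, quantile normalization, and TPM without mitochondrial-encoded and ribosomal RNA genes. A further 3 alternatives were added after seeing the data: an estimated correlation between genes, control replicate 1 and BMH-21 replicate 3 left out together, and removal of each library's trend over transcript length and GC content. No pair of libraries held identical values throughout, and all 6 were counted as separate samples.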

Results

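The transcriptome of HCT116 cells was measured after exposure to BMH-21 and in controls, with 3 libraries in each group. The comparison asks how the messenger RNAs of a colorectal carcinoma line differ after BMH-21, an inhibitor of RNA polymerase I. Synthesis of ribosomal RNA was not measured in these libraries. If the controls were taken at 0 h, time in culture cannot be told apart from the drug. Values are TPM, and sequencing depth per library is unknown. Between 11509 and 12001 genes per library reached 1 TPM. Transcripts encoded by the mitochondrial genome took 20.3% to 26.1% of TPM, and cytosolic ribosomal protein transcripts 16.7% to 23.0%.

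The groups separated along the first principal component, which held 74.7% of the variance, while the second held 13.01%. Control replicate 1 and BMH-21 replicate 3 lay apart from the other libraries of their groups. Their mean squared deviations from the group mean were 0.0586 and 0.0696 on the log2 scale, against 0.0274 to 0.0331 in the other 4 libraries. Both also had the largest mitochondrial shares, 25.8% in control replicate 1 and 26.1% in BMH-21 replicate 3. The ribosomal protein share of 16.7% was also in BMH-21 replicate 3.

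**Figure D1:**
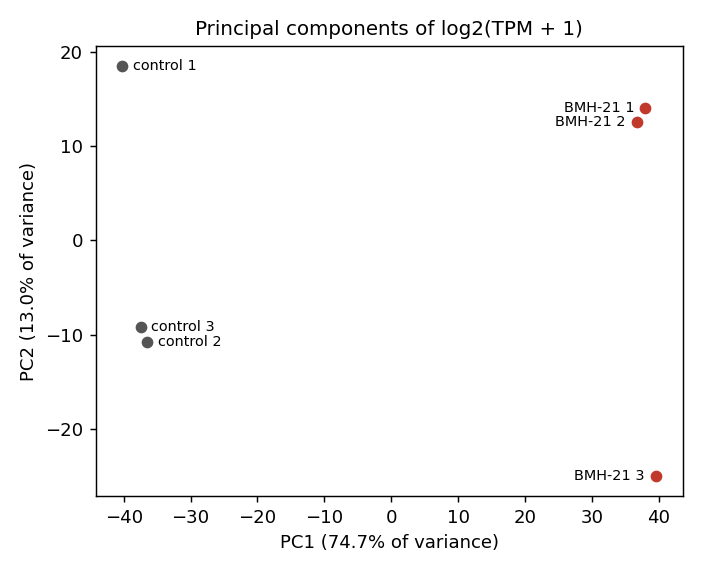
Each point is one library, placed by its scores on the first (74.7% of variance) and second (13.01%) principal components of log2(TPM + 1), in units of the component. The 3 control libraries lie at the left and the 3 BMH-21 libraries at the right, with control replicate 1 and BMH-21 replicate 3 apart from their groups on the vertical axis.

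After BMH-21, p53 target genes were higher and genes of DNA replication and mitosis were lower. Of 12041 genes kept, 4380 (36.4%) were changed, 2340 higher and 2040 lower, by limma with Benjamini-Hochberg adjustment. A change of at least 2-fold was found for 1001 genes, of which 395 were higher and 606 lower. The median log2 fold change of all genes kept was 0.06. The groups did not overlap for 6207 genes, where chance gives 10% of genes. With control replicate 1 and BMH-21 replicate 3 left out, a choice made after seeing the data, 7061 genes were changed, 2917 higher and 4144 lower. The median log2 fold change of all genes was then -0.07, and list counts and medians in that setting are to be read against these values.

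On the log2(TPM + 1) scale, the rise of KRTAP2-3, a keratin-associated protein gene, was the largest among genes meeting the naming rule. By the ratio of mean TPM, SORCS2 rose more, 71.0-fold against 15.7-fold for KRTAP2-3, from a control mean of 0.10 TPM. KRTAP2-3 rose from 4.71 ± 0.77 to 74.2 ± 10.8 TPM (SD, n = 3 per group). On the log2 scale it was followed by CDKN1A, MDM2, F3, SORCS2, SMIM11 and CPA4, with log2 fold changes between 2.75 for CPA4 and 3.40 for CDKN1A. F3, which encodes tissue factor, the initiator of the clotting cascade, went from 9.75 ± 1.94 to 88.0 ± 21.9 TPM. On that scale, the 8 largest falls among genes meeting the rule were those of RRM2, AURKB, PLK1, ASF1B, UBE2C, CDC20, KIF2C and MYBL2. Their log2 fold changes ran from -6.04 for RRM2 to -5.17 for MYBL2. By the ratio of mean TPM, E2F1, CDT1 and GINS2 fell 45.2-fold, 43.9-fold and 42.1-fold, more than CDC20 at 38.8-fold.

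Members of the p53 target list rose almost throughout. Of 52 measured members of the list, 47 were higher, 1 was lower and 4 did not pass the test, with a median log2 fold change of 1.20. The counts were the same adjusted over the list alone. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21 (chromosome 6, 36676460 to 36687339), rose from 220 ± 11.4 to 2341 ± 49.6 TPM (SD, n = 3). That is a 10.6-fold rise of the mean, and a log2 fold change of 3.40 (SE 0.07, limma adjusted p = 5.3e-08). MDM2, which encodes a ubiquitin ligase (chromosome 12, 68808176 to 68850686), rose from 9.59 ± 3.88 to 87.5 ± 12.8 TPM, with an adjusted p of 2.6e-05. TP53I3 and TNFRSF10C, the latter a decoy receptor for the death ligand TRAIL, rose by log2 fold changes of 2.64 and 2.35. The lower member was E2F7, a repressor of cell cycle genes, with a log2 fold change of -0.99. It was named after its value was seen.

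MDM4, a paralog of MDM2, had a log2 fold change of -0.67 that missed the threshold (adjusted p = 0.094). Without BMH-21 replicate 3 it passed, at -0.998 (adjusted p = 0.0065), and it also passed with a trimmed mean scaling (adjusted p = 0.025). The p53 list as a whole moved up by camera (adjusted p = 5.3e-21). With an estimated correlation the adjusted p = 0.29.

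**Figure D2:**
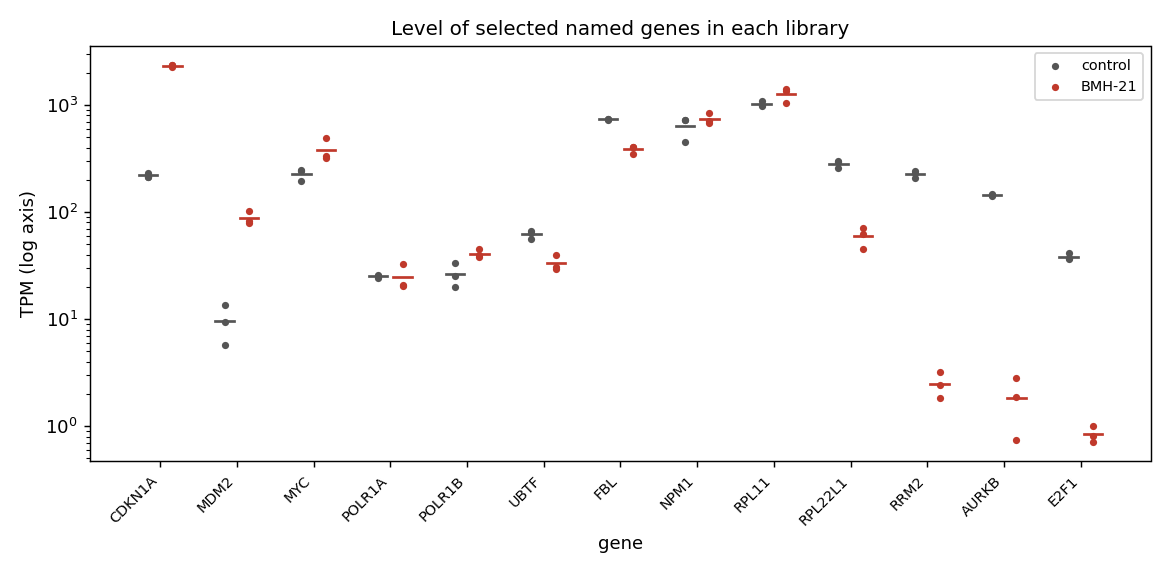
Points are the TPM of each library, on a log axis, for 13 named genes, in grey for control and red for BMH-21, and each bar is the mean of 3 libraries. CDKN1A rose from a mean of 220 to 2341 TPM and RRM2 fell from 227 to 2.49 TPM.

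Genes of the cell division cycle fell together. Of 52 measured genes of the G1/S transition and DNA replication, 51 were lower and none was higher, with a median log2 fold change of -2.72. The exception was CCNE1, which encodes cyclin E1, at 0.08 without passing the test, named after its value was seen. RRM2, a subunit of ribonucleotide reductase (chromosome 2, 10120698 to 10131419), went from 227 ± 18.1 to 2.49 ± 0.70 TPM (SD, n = 3), a log2 fold change of -6.04 (SE 0.15, limma adjusted p = 8.9e-08). CDT1, which licenses replication origins, GINS2, a part of the replicative helicase, and E2F1, the transcription factor of the G1/S program, had log2 fold changes of -5.00, -4.46 and -4.41. All 53 measured genes of G2/M and mitosis were lower, with a median of -3.51. AURKB and PLK1, kinases of chromosome segregation, went from 143 ± 3.30 to 1.81 ± 1.04 TPM and from 171 ± 11.7 to 2.41 ± 0.90 TPM. UBE2C and CDC20, which act with the anaphase-promoting complex, had log2 fold changes of -5.38 and -5.21.

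Counts for both cell cycle lists were the same adjusted over the list alone. Camera gave an adjusted p of 6.2e-40 for G1/S and 1.6e-41 for G2/M. With an estimated correlation the adjusted p = 0.16 for G1/S and adjusted p = 0.19 for G2/M.

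Repair of DNA by homologous recombination and the Fanconi pathway showed the same direction. Of 28 measured members, 22 were lower, 1 was higher and 5 did not pass the test, with a median log2 fold change of -1.31. Adjusted over the list alone, 23 were lower and 1 was higher. RAD54L went from 23.9 ± 3.69 to 0.82 ± 0.14 TPM (SD, n = 3). RAD54L, FANCG and XRCC3 had log2 fold changes of -3.76, -3.54 and -3.41. The higher member was FANCF (0.79), named after its value was seen. Camera gave an adjusted p of 4.1e-12, and with an estimated correlation the adjusted p = 0.36. The median was -2.47 with a pseudocount of 0.1 and -2.39 over members with a mean TPM of at least 5.

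**Figure D3:**
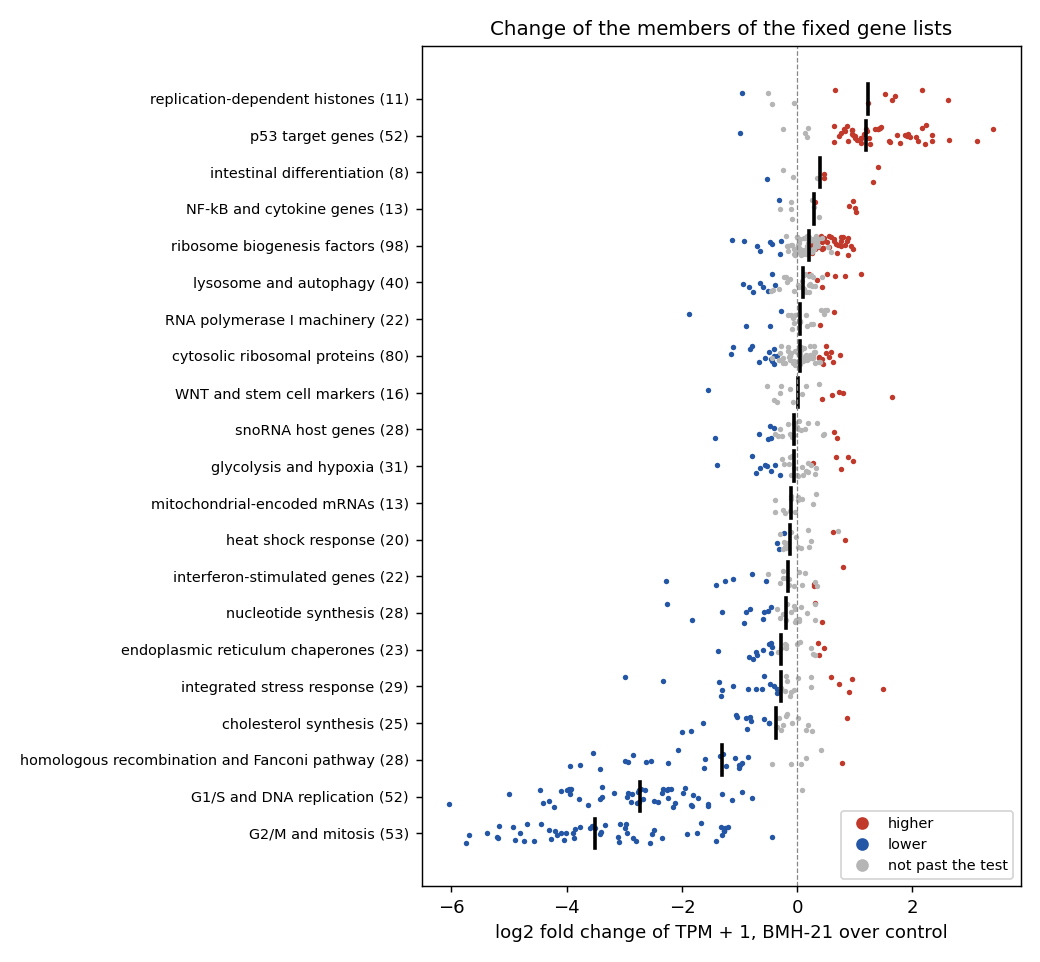
Each point is one measured member of a fixed gene list, placed on the horizontal axis by its log2 fold change of TPM + 1 for BMH-21 over control, with the number measured in brackets; red is higher, blue lower and grey not past the test. Black bars are list medians, from -3.51 for G2/M and mitosis to 1.24 for replication-dependent histones.

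Components of the RNA polymerase I machinery did not move as a group. Of 22 measured members, 2 were higher, 4 were lower and 16 did not pass the test, and adjusted over the list alone 1 was higher and 4 were lower. TCOF1, which encodes the nucleolar protein treacle, fell from 50.3 ± 0.37 to 13.2 ± 2.61 TPM (SD, n = 3). UBTF, the upstream binding factor of ribosomal DNA (chromosome 17, 44205033 to 44221626), fell from 62.2 ± 4.93 to 33.2 ± 5.33 TPM (log2 fold change -0.89, SE 0.12, limma adjusted p = 0.00069). POLR1D, a subunit shared with RNA polymerase III, had a log2 fold change of -0.47. POLR1B, the second largest subunit of the enzyme, rose from 26.2 ± 6.56 to 40.7 ± 3.82 TPM (adjusted p = 0.017), a call that was lost with no filter on low values (adjusted p = 0.056). The largest subunit, POLR1A, was at 25.04 ± 0.81 and 24.7 ± 7.22 TPM (adjusted p = 0.85). Without BMH-21 replicate 3, POLR1A passed as lower, at -0.27 (adjusted p = 0.033). RRN3, an initiation factor of the polymerase, had a log2 fold change of 0.49 that missed the threshold (adjusted p = 0.062) and passed with a trimmed mean scaling (adjusted p = 0.036). The list median was 0.06, while the mean was -0.01 and camera gave a downward direction (adjusted p = 0.98). In this list, 5 members were higher and 5 lower without BMH-21 replicate 3, and with control replicate 1 also left out 8 were higher and 10 lower. Quantile normalization gave 7 higher and 4 lower.

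Ribosome biogenesis factors were higher on balance by a small amount. Of 98 measured members, 32 were higher, 8 were lower and 58 did not pass the test, with a median log2 fold change of 0.21, and the counts were the same adjusted over the list alone. RPF2 and PNO1, assembly factors of the large and small subunit, rose by 0.97 and 0.93. FBL, the methyltransferase fibrillarin, fell from 734 ± 13.8 to 387 ± 32.7 TPM (SD, n = 3), and NOP53 had a log2 fold change of -1.14. The nucleolar proteins NPM1 and NCL did not pass the test, with log2 fold changes of 0.26 and 0.00. NCL passed as lower with control replicate 1 and BMH-21 replicate 3 left out, at -0.40 (adjusted p = 0.00062). Camera gave an adjusted p of 0.0099 for the list, and with an estimated correlation the adjusted p = 0.72. Without control replicate 1 and BMH-21 replicate 3, 37 members were higher and 22 lower, and the median was 0.07. Without BMH-21 replicate 2, 21 were higher and 6 lower, and without control replicate 1 the median was 0.10.

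Ribosomal protein transcripts showed changes in both directions. Of 80 measured members, 10 were higher, 13 were lower and 57 did not pass the test, and adjusted over the list alone 8 were higher and 12 were lower. RPL28, RPL3, RPS9 and RPL10A fell, with log2 fold changes of -1.14, -1.11, -0.81 and -0.78. RPL5 and RPL11, whose proteins bind MDM2, had log2 fold changes of 0.02 and 0.29 and did not pass the test, and neither did RPL22 at 0.22. Without BMH-21 replicate 3, RPL11 and RPL22 passed as higher, at 0.42 and 0.36 (adjusted p = 0.0016 and 0.0033). RPL22L1, a paralog of RPL22, fell from 284 ± 21.6 to 59.2 ± 12.8 TPM (SD, n = 3; log2 fold change -2.26, limma adjusted p = 8.0e-06). The list median was 0.04, the mean was -0.01 and camera gave a downward direction (adjusted p = 0.80). This list rested on BMH-21 replicate 3: without it 43 members were higher and 17 lower, and camera gave an upward direction (adjusted p = 0.0016). Without any other 1 library, 3 to 5 members were higher and 8 to 13 lower. With a trimmed mean scaling, 2 were higher and 7 lower, and the median fell below 0, to -0.01. Quantile normalization gave 23 higher and 25 lower.

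Among snoRNA host genes, 2 of 28 measured members were higher, 6 were lower and 20 did not pass the test. SNHG7 had a log2 fold change of -1.43 and SNHG25 one of 0.68, and the list did not pass camera (adjusted p = 0.41). Without BMH-21 replicate 3, 5 were higher and 7 lower, and without control replicate 2 or BMH-21 replicate 2, 2 were higher and 3 lower.

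Several biosynthetic lists moved down. For cholesterol synthesis, 12 of 25 measured genes were lower, 1 was higher and 12 did not pass the test, with a median log2 fold change of -0.36, and adjusted over the list alone 15 were lower. EBP and ACAT2 fell from 177 ± 6.40 to 43.8 ± 5.20 and from 53.4 ± 1.77 to 14.2 ± 0.43 TPM (SD, n = 3), while INSIG1 and FDPS had log2 fold changes of -1.63 and -1.06. For nucleotide synthesis, 10 of 28 were lower, 2 were higher and 16 did not pass the test, also adjusted over the list alone, with a median of -0.19. TYMS, which encodes thymidylate synthase, and SHMT1 had log2 fold changes of -1.83 and -1.30. Camera gave adjusted p of 1.3e-05 for cholesterol synthesis and 0.0098 for nucleotide synthesis. With an estimated correlation the adjusted p = 0.36 for the former and adjusted p = 0.72 for the latter. With control replicate 1 and BMH-21 replicate 3 left out, 20 cholesterol genes were lower and 1 higher with a median of -0.64, and 20 nucleotide synthesis genes were lower and 4 higher. Without BMH-21 replicate 1 or 2, 9 nucleotide synthesis genes were lower and 0 higher.

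Genes of the integrated stress response and of endoplasmic reticulum folding also moved down on balance. In the stress response list, 14 of 29 measured genes were lower, 5 were higher and 10 did not pass the test, with a median of -0.29, and adjusted over the list alone 14 were lower and 6 higher. ATF4, the transcription factor of this response, fell from 457 ± 47.9 to 181 ± 42.3 TPM (SD, n = 3). CHAC1 and PHGDH had log2 fold changes of -2.98 and -2.33, while CBS had one of 1.49. CBS went from 0.07 ± 0.05 to 2.01 ± 0.13 TPM, so its control level was near the floor. Of 23 endoplasmic reticulum chaperone genes, 10 were lower, 3 were higher and 10 did not pass the test, also adjusted over the list alone, with a median of -0.28. HERPUD1 and XBP1 had log2 fold changes of -1.38 and -0.72. Camera gave adjusted p of 0.012 for the stress response and 0.014 for chaperones. With an estimated correlation the adjusted p = 0.72 for both. Without BMH-21 replicate 1, 9 stress response genes were lower and 4 higher, and their median was -0.17 without control replicate 2. Leaving out control replicate 1 and BMH-21 replicate 3 gave 16 chaperone genes lower and 3 higher, with medians of -0.52 for chaperones and -0.45 for the stress response. The chaperone median was -0.47 without control replicate 1 and -0.43 over members with a mean TPM of at least 5.

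Most of the few replication-dependent histone genes that were measured were higher. Of 46 in the table, 11 were kept, of which 7 were higher, 1 was lower and 3 did not pass the test, with a median log2 fold change of 1.24. Adjusted over the list alone, 7 were higher and 2 were lower. H2BC5 rose from 2.36 ± 0.36 to 19.6 ± 1.39 TPM and H1-2 from 8.74 ± 0.59 to 42.4 ± 1.39 TPM (SD, n = 3), while H2BC12 and H2AC6 had log2 fold changes of 1.69 and 1.64. These genes have near-identical copies, so the split of reads between members is uncertain. MALAT1, a nuclear RNA without a normal poly(A) tail, was also higher, at 7.14 ± 0.48 TPM in controls and 30.2 ± 1.19 TPM after BMH-21 (limma adjusted p = 4.3e-06), and was named after its value was seen. Camera gave an adjusted p of 0.014, and with an estimated correlation the adjusted p = 0.36. With no filter on low values, 7 of 36 members were higher and 7 lower, and the direction turned downward (adjusted p = 0.67). Without BMH-21 replicate 3, 7 of 11 were higher and 3 lower. With the length and GC trend removed, 10 members were kept, 6 of them higher and 1 lower, and the camera adjusted p was 0.053.

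The remaining lists did not pass camera. Of 22 interferon-stimulated genes, 6 were lower and 3 higher, with OAS3 at a log2 fold change of -2.28 (camera adjusted p = 0.093). Of 13 NF-kB and cytokine genes, 5 were higher and 1 lower, with CSF1 and ICAM1 at 1.03 and 1.01 (adjusted p = 0.17). Of 8 measured genes of intestinal differentiation, 4 were higher and 1 was lower, with EMP1 at 1.40 (adjusted p = 0.16). Of 16 WNT and stem cell markers, 5 were higher and 1 was lower (adjusted p = 0.88). CCND1, which encodes cyclin D1, rose from 105 ± 11.9 to 338 ± 92.3 TPM (SD, n = 3), and MYC rose from 228 ± 28.2 to 383 ± 96.0 TPM (log2 fold change 0.73, SE 0.16, limma adjusted p = 0.0090). Glycolysis and hypoxia genes went both ways, with 5 higher and 9 lower of 31 (adjusted p = 0.54), including SLC2A1 at 0.89 and ALDOC at -1.40. Lysosome and autophagy genes did so too, with 7 higher and 8 lower of 40, including DRAM1 at 1.11 and GLA at -0.93. That list had a median of 0.10 while camera gave a downward direction (adjusted p = 0.98). For the heat shock response, 2 of 20 genes were higher and 3 lower, with HSPA4L at 0.83. That call was lost without control replicate 1 or 2 or BMH-21 replicate 1, with an adjusted p of 0.053 to 0.076. The median was -0.13 while the mean was 0.02, and camera gave a downward direction (adjusted p = 0.60). None of 13 mitochondrial-encoded mRNAs passed the test in limma, none had an unadjusted p under 0.05, and MT-CO2 was at 27220 ± 1841 and 28670 ± 517 TPM. Of these mRNAs, 4 were lower without BMH-21 replicate 3, and with quantile normalization 1 was higher and 2 were lower. With control replicate 1 and BMH-21 replicate 3 left out, 4 were higher, MT-CO2 among them (adjusted p = 0.016), and 7 were lower.

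The counts of several of these lists moved when 1 library was left out. In the heat shock list, the count higher ranged from 0 without BMH-21 replicate 1 to 2, and the count lower from 0 to 6, the latter without BMH-21 replicate 3, while quantile normalization gave 4 higher and 1 lower. Without control replicate 1, 2 or 3, 3 WNT genes were higher and 1 was lower, and without BMH-21 replicate 3, 5 were higher and 3 lower. Without control replicate 2 or 3 or BMH-21 replicate 2, 1 interferon gene was higher and 5 were lower. Without BMH-21 replicate 2, 3 NF-kB genes were higher and 0 lower, and without control replicate 3, 5 glycolysis genes were higher and 5 lower. For intestinal differentiation, 4 genes were higher and 0 lower without control replicate 2 or 3 or BMH-21 replicate 1 or 2. Leaving out BMH-21 replicate 3 gave 3 higher and 2 lower in that list.

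Adjusted over the list alone, these lists had 3 higher and 7 lower for interferon, 5 and 1 for NF-kB, 4 and 1 for intestinal differentiation, and 5 and 2 for WNT. The same counts were 7 and 10 for glycolysis, 8 and 9 for lysosome, 1 and 2 for heat shock, 0 and 0 for mitochondrial-encoded mRNAs, and 2 and 6 for snoRNA hosts. Markers of other cell types were too few to test, with 3 fibroblast, 1 leukocyte and 1 endothelial marker kept, and their counts were the same adjusted over the list alone. ACTA2, a smooth muscle actin gene, rose from 4.49 ± 0.55 to 30.4 ± 0.79 TPM (SD, n = 3), whereas FBLN1, COL1A1, CD68 and ESAM fell, with log2 fold changes of -1.05, -0.61, -1.60 and -1.34. The call of COL1A1 was lost without any 1 control library and without BMH-21 replicate 1 or 2, with an adjusted p of 0.061 to 0.14.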

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

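The estimated correlation, the left-out pair of libraries and the removed length and GC trend were chosen after seeing the data. Across the alternatives set before the data were examined, the count of genes changed lay between 3173 (without BMH-21 replicate 2) and 5395 (quantile normalization), and every called gene shared with the original fit had the same sign. With control replicate 1 and BMH-21 replicate 3 left out together, 7061 genes were changed and 4144 lower. Of the original 4380, 4304 were called again. These libraries had the largest deviations from their group means, so leaving them out lowers the spread within groups and favours more calls. Whether that accounts for all the added calls was not tested. Deviations of same-numbered libraries from their group means correlated at 0.04, -0.14 and 0.02. Such deviations cancel out within a group, so weak correlations cannot decide whether the replicate numbers pair the samples. A replicate block gave 4608 genes, and RRN3 and MDM4 passed with it (limma adjusted p = 0.026 and 0.014). No other call changed with it among named genes and lists. With no filter, the histone list turned downward (adjusted p = 0.67), with 36 members kept in place of 11, and the NF-kB and interferon lists passed (0.044 and 0.049). The interferon list also passed without the variance trend (camera adjusted p = 0.045). The histone list missed the threshold with the length and GC trend removed (camera adjusted p = 0.053). That setting holds only genes matched to the annotation, so 10 histone members were kept in place of 11, and 6 were higher. The effects of the removed trend and of the missing member were not told apart, and the cause was not tested. Over 12027 matched genes, the log2 fold change correlated with GC content at -0.23 (Spearman). Median GC was 49.3% in genes higher and 55.9% in genes lower, and the source of this relation was not tested. With the trend removed, 4839 genes were changed, 2717 higher and 2122 lower, and 4006 of the original 4380 were called again. For ribosomal proteins, adjusted p ranged from 0.0016 to 0.91 over libraries left out in turn, lowest and upward without BMH-21 replicate 3; it was 0.0013 with both libraries out. With an estimated correlation, adjusted p were 0.29 for p53 targets, 0.16 for G1/S, 0.19 for G2/M, 0.36 for histones, recombination and cholesterol, and 0.72 for ribosome biogenesis, stress response, chaperones and nucleotide synthesis. Of 106 named genes, none reversed a call under any alternative run. Depth is unknown, so no limit from counting can be given.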

Other observations

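The gene families in this and the next paragraph were chosen after the values were seen, from 215 symbol prefixes with at least 8 genes kept and from known functions. Their p-values do not account for that choice. Keratins, the intermediate filament proteins of epithelial cells, rose: 9 of 12 measured genes were higher and none was lower, with a median log2 fold change of 1.34. KRT8 went from 2813 ± 129 to 6586 ± 484 TPM (SD, n = 3) and KRT19 from 995 ± 25.1 to 3292 ± 207 TPM. S100 genes, which encode small calcium-binding proteins, had 10 of 11 members higher and none lower. S100A6 rose from 2394 ± 68.2 to 7338 ± 402 TPM. Kallikrein-related peptidase genes had 5 of 6 members higher, including KLK6 at a log2 fold change of 1.98, and KLK1 lower at -0.99. Tubulins fell, with 10 of 12 lower and none higher, and TUBA1B went from 2930 ± 131 to 335 ± 31.5 TPM. Over 7 families tested, camera gave adjusted p of 1.2e-06 for keratins, 2.4e-06 for S100, 0.00022 for kallikreins and 1.2e-08 for tubulins. With an estimated correlation the adjusted p = 0.042 for each of these 4. This adjustment ran over the chosen families only, while that of the fixed lists ran over more lists. With an estimated correlation, G1/S and G2/M had unadjusted camera p of 0.0077 and 0.019. The adjusted values thus cannot show that these families pass a test which those fixed lists fail. The medians of these 4 families kept their sign under the 4 scalings run, with 8 to 11 S100 genes higher, and 1 tubulin gene was called higher under 3 of them.

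Nucleoporins had 10 of 21 members lower and 1 higher, and up to 15 lower under another scaling (camera adjusted p = 6.2e-05; with an estimated correlation adjusted p = 0.33). Genes of desmosomes and gap junctions had 5 of 12 higher and none lower (camera adjusted p = 0.0045; with an estimated correlation adjusted p = 0.16). Antigen presentation by MHC class I had 3 of 13 higher and 2 lower and did not pass (adjusted p = 0.29), with 2 to 6 higher and 1 or 2 lower over the scalings run, although TAP1 rose by 1.37. CYP1A1 and TIPARP, targets of the aryl hydrocarbon receptor, rose by log2 fold changes of 2.26 and 1.85. A hypothesis that targets of this receptor may have risen as a group was tested on 8 others, of which 4 were kept: 2 were higher, AHRR and CYP2S1, and 2 did not pass, ALDH3A1 and NQO1, so the aryl hydrocarbon receptor explanation stays open with so few genes.

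In the tests below, those of the histone genes, of the scaling and the left-out libraries for ribosome biogenesis, and of the splits were chosen after the results were seen. Control replicate 1 and BMH-21 replicate 3 lay apart from their groups. A trend over transcript length and GC content could account for part of this. With the trend removed, the mean squared deviation was still 2.09 times that of the other BMH-21 libraries, from 2.24 before, and 1.85 times that of the other control libraries, from 2.12, which argues against the trend as the whole difference. A smaller response in BMH-21 replicate 3 is argued against by the slope of its log2 changes on those of the other BMH-21 libraries. The slope was 0.97 over 1074 genes changed at least 2-fold without that library. For BMH-21 replicates 1 and 2, taken the same way, it was 0.958 and 0.960. All these log2 changes share the same control mean, which by itself ties them together. Other differences in library preparation or culture stay open and were not tested.

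Of 11 histone genes kept, 7 were higher, while 51 of 52 G1/S genes were lower. A candidate explanation is that the libraries held mostly polyadenylated RNA, so that histone mRNAs without a poly(A) tail were hardly measured: 34 of the 46 histone genes lay under 1 TPM in the controls, where the median of the G1/S list was 37.7 TPM. The members that rose may then be the few that also make polyadenylated transcripts. MALAT1, which lacks a normal poly(A) tail, rose in the same libraries, from 7.14 ± 0.48 to 30.2 ± 1.19 TPM, so a larger share of RNA without such a tail in the BMH-21 libraries stays open, as does a response of histone genes to BMH-21 itself, and none of these was tested. Reads moved only among the 24 H2A and H2B genes of the list, with no change of their sum, are argued against. Their summed TPM rose 3.09 times, from 31.6 ± 2.06 to 97.5 ± 0.78 TPM (SD, n = 3). Copies outside the list were not summed, so reads moved from those copies stay open.

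Ribosome biogenesis genes were higher on balance. The choice among the scalings run is argued against as the cause, because the list median was at least 0.15 under each of them. None of these scalings can show a change in total RNA per cell. Without the libraries that lay apart the list median fell from 0.21 to 0.07, but the median of all genes fell too, from 0.06 to -0.07. The list stayed 0.13 above all genes, against 0.15 in the original fit. This argues against these libraries as the source of that excess, although it was 0.10 without control replicate 1 alone. With the length and GC trend removed, the list median was 0.14 above the median of all genes. The camera call was lost with an estimated correlation (adjusted p = 0.72). So was that of every other fixed list, including G2/M with all 53 measured genes lower (adjusted p = 0.19). That loss therefore cannot decide for or against this list. The call rests on the preset correlation, so a small rise caused by BMH-21 is a hypothesis.

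The 6 libraries allow 10 splits into groups of 3, too few for a share under 0.05. The real split gave 4380 genes changed, 2340 higher, 2040 lower and 1001 changed at least 2-fold. The highest of the other splits gave 1 changed, 0 higher, 1 lower and 1 changed at least 2-fold. Every other split mixes treated and control libraries within its groups, so the treatment difference adds to the spread there. Few gene calls were thus fixed in advance in those splits, and their counts do not give a level of chance for the gene calls. For the gene lists with a preset correlation, the real split called 10 lists and the highest other split 11, and 4 of the 10 splits, the real one included, called at least as many. Each other split keeps unequal numbers of treated libraries on its sides, so part of the treatment difference remains in it. The number of lists called did not set the real split apart. Because of that remaining difference, these counts give no level of chance and cannot decide for or against the list calls.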
